A study of Mus musculus with 3 samples.

How the data were processed

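Total RNA of liver kept in RNAlater was extracted on columns, and biotin-labelled cRNA was made by the array maker's standard protocol, per the labels' protocols. Affymetrix mouse arrays measured 1 pool of 6 livers in each of 3 groups. The probe set values were made with MAS5, per the submitters' processing notes. Its version, scaling target and detection calls are not given in the sources used here. The deposited value table holds log2 signals of 45101 probe sets. On the linear scale its trimmed mean, without the lowest and highest 2% of probe sets, was 500.0 on each of the 3 arrays, so the arrays had been scaled to a common target. The values reach down to a log2 of 0, which 319, 155 and 124 probe sets hold in young control, old control and old Chlorella.

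The authors also deposited a table of log2 ratios of each array over the median of all samples, for 19882 probe sets, with 5620 blank cells. The rule behind the blanks is not given in the sources used here. Differences between its columns equal those of the value table within 0.001. Of the 15793 probe sets with no blank, 1.48% had a median ratio within 0.001 of 0, so the denominator is not the median of these 3 arrays. The ratios were used only as differences between arrays, in which the denominator cancels. The column of that table for old mice on normal food was matched by its name, since the other old sample has a column named for Chlorella.

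Gene symbols came from the platform annotation and were updated through Entrez gene identifiers against a RefSeq gene table of assembly GRCm38.p6, which matched 34754 probe sets. Of all probe sets, 34958 had 1 symbol, 932 had several and 9211 were not listed, 64 control probe sets among these. Probe sets with several symbols or none name no gene here. No genome build is named in the files, so no coordinates are given. The gene table also supplied the genomic length of genes, which 99.9% of the 10527 genes above the floor on all arrays had.

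The detection floor was the 50th percentile of all probe sets on each array, a signal of 67.6 in young control, 80.4 in old control and 88.0 in old Chlorella. Each of 18194 genes was represented by its brightest probe set by mean log2 signal, and 12997 genes above the floor on at least 1 array counted as measured. Values under the floor were raised to it, and a difference of 2-fold or more with 1 array at the floor is a lower bound, written as at least N-fold. Because the floors differ between arrays, raising a value turned the sign of 247 age differences and 155 diet differences, of sizes up to 0.25 and 0.13 on the log2 scale and so with 0 at 1.5-fold. One of them is the diet difference of Slco1a1, and these values enter the list medians. A gene at the floor on both arrays compared got no difference, a rule added after the files were seen because the floors differ between arrays. Differences are log2 of old control over young control, of old Chlorella over old control and of old Chlorella over young control, called age and diet differences for the first and second. Genes at 2-fold or more were counted, and members of gene lists count as higher or lower at 1.5-fold or more.

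With 1 array per group no test across genes applies, and neither p-values nor standard errors are given. The median of each of 35 gene lists was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A median outside their central 95% stands apart on these arrays, which says nothing about other mice. The lists cover hepatocyte functions, lipid, bile acid and drug metabolism, stress responses, immune cells, other cell types of the liver and neighbouring tissues. Of 982 listed genes 890 were on the arrays, with list members counted once per list, and some genes belong to several lists. Measurement noise was taken from the 2 brightest probe sets of 4277 genes above the floor on all arrays, in 5 bins of signal, and 100 sets of 3 arrays were simulated from it. The simulation leaves out variation between animals, between pools and between hybridizations that act on all probe sets of a gene. Noise of genes under the floor on any array was not measured and may be larger than simulated.

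Named genes followed a rule. For the age and the diet difference it took the 10 highest and 10 lowest genes above the floor on both arrays, leaving out clone names and predicted genes, then up to 3 bounds in each direction. For each list outside the random range it took up to 4 members with the largest difference in the direction of the median. For opposed differences it took the 10 largest age differences opposed by at least 0.5 of their size and the 5 largest that were not, among genes above the floor on all 3 arrays. Acaca, Scd1, Me1, Insig2, Ndufs1, Uqcrc1, Ndufv1, Xist, Hnf4a, Apob, Cebpa, Nr1d1, Per2, Arntl, Cry1, Hbb-b2 and Alas2 were named after their values were seen, as were the age values of Saa1.

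On arrays simulated for the diet comparison with 200 genes altered, 5.5% of genes altered 1.5-fold reached a 2-fold difference, as did 46.5% of those altered 2-fold and 97.5% of those altered 4-fold. In these runs over 12046, 12035 and 12024 genes, 51, 69 and 66 unaltered genes reached 2-fold. Of 200 random lists of 20 genes, 4.5% lay outside the central 95%. The alternatives were quantile normalization, centring on the median of measured genes, floors at the 40th and 70th percentile and no floor. Further ones were the ratio table, the mean of all a gene's probe sets, and leaving out probe sets ending in _x_at, _s_at or _a_at. These endings mark sequence shared between transcripts, which may be of 1 gene, and such probe sets are called probe sets of shared sequence. Removal of a trend with intensity in 50 bins and of a trend with genomic gene length in 20 bins, and leaving out differences whose sign the floor turned, were chosen after seeing the data. The floor, the lists, the rule for named genes and the other alternatives were fixed before the data were examined. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.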

Results

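Liver gene expression was measured in 3 groups of female mice of the inbred strain BALB/c. The young control group was 10 weeks old and the old control group 50 weeks old, and both ate normal food. The old Chlorella group was also 50 weeks old and ate food with 2.0% powder of Chlorella, a single-celled green alga. RNA of 6 mice was pooled in each group, and each pool was read on 1 array, so the number of arrays limits the precision. With 1 array per group no difference has a replicate check, no p-values are given, and each value describes these 3 pools. The title of the series speaks of mice sensitized to ovalbumin, an egg protein used as an allergen, but the sample labels do not, so sensitization enters no comparison.

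Each array held 45101 probe sets. The median signal was 67.6 in young control, 80.4 in old control and 88.0 in old Chlorella, and these medians served as the detection floors. A total of 12997 genes lay above the floor on at least 1 array. Across these 12997 genes, with values under the floor raised to it, log2 signals of the 2 old pools had a Pearson correlation of 0.985. Old control with young control had 0.945. Genes are not independent replicates. Between probe sets of the same gene, the SD of a log2 difference was 0.43 for old against young control and 0.29 for old Chlorella against old control. This spread covers measurement within these pools and not the variation between animals.

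The first comparison asks how the liver of older mice on normal food differed from that of young mice. Transcripts of immune cells were higher in old control. Those of fatty acid oxidation, bile acid handling, drug-metabolizing cytochromes P450, the unfolded protein response with ATF4 targets, and male-biased liver genes were lower. Both old arrays were also more weighted to the 3′ end of control transcripts, as given below, which cannot be told apart from age here. Of 12580 genes, 1078 were at least 2-fold higher and 871 at least 2-fold lower in old control. The balance depended on the processing: 1467 were higher and 543 lower after centring on the median of measured genes, and 973 and 956 after removal of a trend with gene length. Arrays simulated with no difference, with noise taken from probe sets of the same gene, gave a mean of 370 such genes in both directions and at most 422. That noise came from genes above the floor on all arrays. It may be too small for the 1707 differences with 1 array at the floor. Of 35 gene lists, 7 had a median above and 9 a median below the central 95% of random lists matched on mean signal, where 1.75 in all would be outside if lists were random.

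B cell and plasma cell genes were higher in old control in 15 of 20 measured members and lower in 0, with a median log2 difference of 1.16, where random lists ranged from −0.36 to 0.35. Ms4a1, the B cell surface protein CD20, was 7.49-fold higher, Jchain, which joins secreted immunoglobulin units, 6.15-fold, and Cd79b, part of the B cell receptor, 4.64-fold. Macrophage, Kupffer cell and monocyte genes were higher in 21 of 30 and lower in 1, with a median of 0.90. Among them Tyrobp, a signalling adaptor of myeloid cells, was 4.27-fold higher, the costimulatory protein gene Cd86 4.11-fold, and Vsig4, a receptor of Kupffer cells, 3.54-fold. Spic, a transcription factor of red pulp and Kupffer macrophages, was at least 5.31-fold higher because it lay under the floor in young control. T and NK cell genes were higher in 15 of 26 with a median of 0.63, led by the chemokine receptor gene Cxcr6 at 4.27-fold and the granzyme gene Gzma at 4.13-fold.

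MHC class II genes, which present antigen, were higher in 6 of 7 with a median of 1.08, and H2-Eb1, H2-Ab1 and H2-Aa were 2.18-fold, 2.15-fold and 2.11-fold higher. The neutrophil, eosinophil and mast cell list had 8 measured members, of which 5 were higher, with a median of 0.81. Its calcium-binding neutrophil proteins S100a8 and S100a9 were 8.89-fold and 7.20-fold higher. That list was inside the random range when probe sets with suffixes for shared sequence were left out. Of the cytokine list, 12 of 29 genes were measured, 6 were higher and 1 was lower, with a median of 0.55. The neutrophil attractant gene Cxcl1 was 5.14-fold higher, the eosinophil attractant gene Ccl24 3.74-fold and Il1b 3.26-fold. The median of the cytokine list was inside the random range without those probe sets, and when a trend with gene length was removed.

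Both old arrays were more weighted to the 3′ end of control transcripts than the young array, as given with the subunits of oxidative phosphorylation. This may bear on the lists lower in old control as well as on the higher ones, which was not tested directly. Against random lists matched on genomic gene length as well as signal, the neutrophil list had a percentile of 99.5, MHC class II genes 99.8 and the other 3 immune cell lists 99.98 or more.

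Fatty acid oxidation and PPARa target genes were lower in old control in 14 of 26 and higher in 0, with a median of −0.79, where random lists ranged from −0.30 to 0.45. Vnn1, a pantetheinase under PPARa control, was 7.69-fold lower, the acyl-CoA thioesterase gene Acot1 3.65-fold, and Ppara itself 2.77-fold. Hadhb, a subunit of the mitochondrial trifunctional protein, was 2.44-fold lower by its brightest probe set, but its 3 probe sets ran from −1.28 to 1.09 on the log2 scale. Bile acid genes were lower in 12 of 21 and higher in 4, with a median of −0.69. Slco1a1, an organic anion transporter of hepatocytes, was 26.1-fold lower, with signals of 2248 in young control and 86.2 in old control. The bile acid feedback regulator Nr0b2 was 2.38-fold lower, and Cyp8b1, which makes cholic acid, 2.33-fold. Slc51b, a bile acid exporter subunit, was at least 4.70-fold higher because it lay under the floor in young control.

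Cytochrome P450 genes were lower in 15 of 32 and higher in 2, with a median of −0.49. The largest differences were in Cyp2d9 at 6.25-fold, Cyp2f2 at 5.14-fold, Cyp2c54 at 4.16-fold and Cyp3a16 at 3.28-fold. Genes of the unfolded protein response and ATF4 targets were lower in 15 of 27 and higher in 0, with a median of −0.63. Pdia4, a disulfide isomerase, was 2.60-fold lower, Ppp1r15a, which restores translation after stress, 2.57-fold, and Sel1l, part of the degradation machinery of the endoplasmic reticulum, 2.57-fold. Pdia6 was 2.54-fold lower by its brightest probe set, while its other probe set was higher by 1.51 on the log2 scale.

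Male-biased liver genes, which male mice express more than females, were lower in 11 of 19 and higher in 2, with a median of −0.67. Besides Slco1a1 and Cyp2d9, Serpina4-ps1 was 10.3-fold lower and Cyp1a2 3.04-fold. Hsd3b5, a steroid-metabolizing enzyme of this list, was at least 20.8-fold lower because it lay under the floor in old control. Of 20 measured members of this list, 7 also belong to other lists. Female-biased liver genes had a median of −0.30, inside the random range, with 8 of 22 lower and 3 higher.

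Gluconeogenesis and amino acid catabolism genes had a median of −0.48, with 5 of 15 lower and 0 higher. Pck1, the rate-limiting enzyme of gluconeogenesis, was 2.76-fold lower by its brightest probe set, and its 3 probe sets ran from −2.36 to 1.05. Oat was 1.86-fold lower and Pcx 1.64-fold. From young to old control, the log2 signal of the Pcx control probe sets went from 10.89 to 8.43 at the 5′ end. At the 3′ end it went from 12.44 to 11.76, so the fold of Pcx depends on probe position. This list was inside the random range after quantile normalization, after removal of an intensity trend and without probe sets of shared sequence. The acute phase list had a median of −0.30 with 10 of 29 lower and 4 higher. Its members went both ways: Serpina3n was 2.31-fold lower, Lcn2 2.30-fold and Lbp 2.25-fold, while Saa1, a serum amyloid, was 2.96-fold higher. It was inside the range when all probe sets of a gene were averaged.

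Cell cycle genes had a median of −0.30 with 7 of 29 lower and 4 higher. The cyclin gene Ccnb2 was 2.20-fold lower, Cdk1 1.78-fold and Cdc20 1.75-fold. Ccnb2 and Cdk1 had signals of 91.5 and 96.9 in old control, near its floor of 80.4. The list was inside the random range with a floor at the 70th percentile and in the ratio table. Pancreatic acinar genes had a median of −0.40 with 4 of 12 lower and 0 higher. They lay near the floor, and only Cel and Prss2, both 1.23-fold lower, had a negative difference with signals above it on both arrays.

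Subunits of oxidative phosphorylation were higher in 33 of 56 and lower in 3, with a median of 0.63 and a random range from 0.09 to 0.56. Ndufs4 was 3.40-fold higher, Atp5e 2.87-fold, Ndufb2 2.81-fold and Ndufc1 2.54-fold, while Ndufs1 was lower with a log2 difference of −0.96, Uqcrc1 with −0.64 and Ndufv1 with −0.60. The 3 Ndufs4 probe sets ran from 0.27 to 2.11. The 2 Ndufb2 probe sets above the floor on both arrays gave 1.49 and 1.56. Without probe sets of shared sequence Ndufb2 changed sign, in a probe set at the floor on 1 array. The median was inside the random range after quantile normalization and after removal of a trend with intensity or gene length. Control probe sets at the 3′ end relative to the 5′ end of Pcx gave a signal ratio of 2.92 in young control, 10.1 in old control and 10.7 in old Chlorella, and those of Actb 1.74, 2.27 and 2.31. Over 10514 genes, the age difference had a Spearman correlation of −0.14 with genomic gene length across genes, which are not independent. Genes up to 2 kb had a median age difference of 0.39 and genes over 100 kb one of −0.19.

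**Figure D1:**
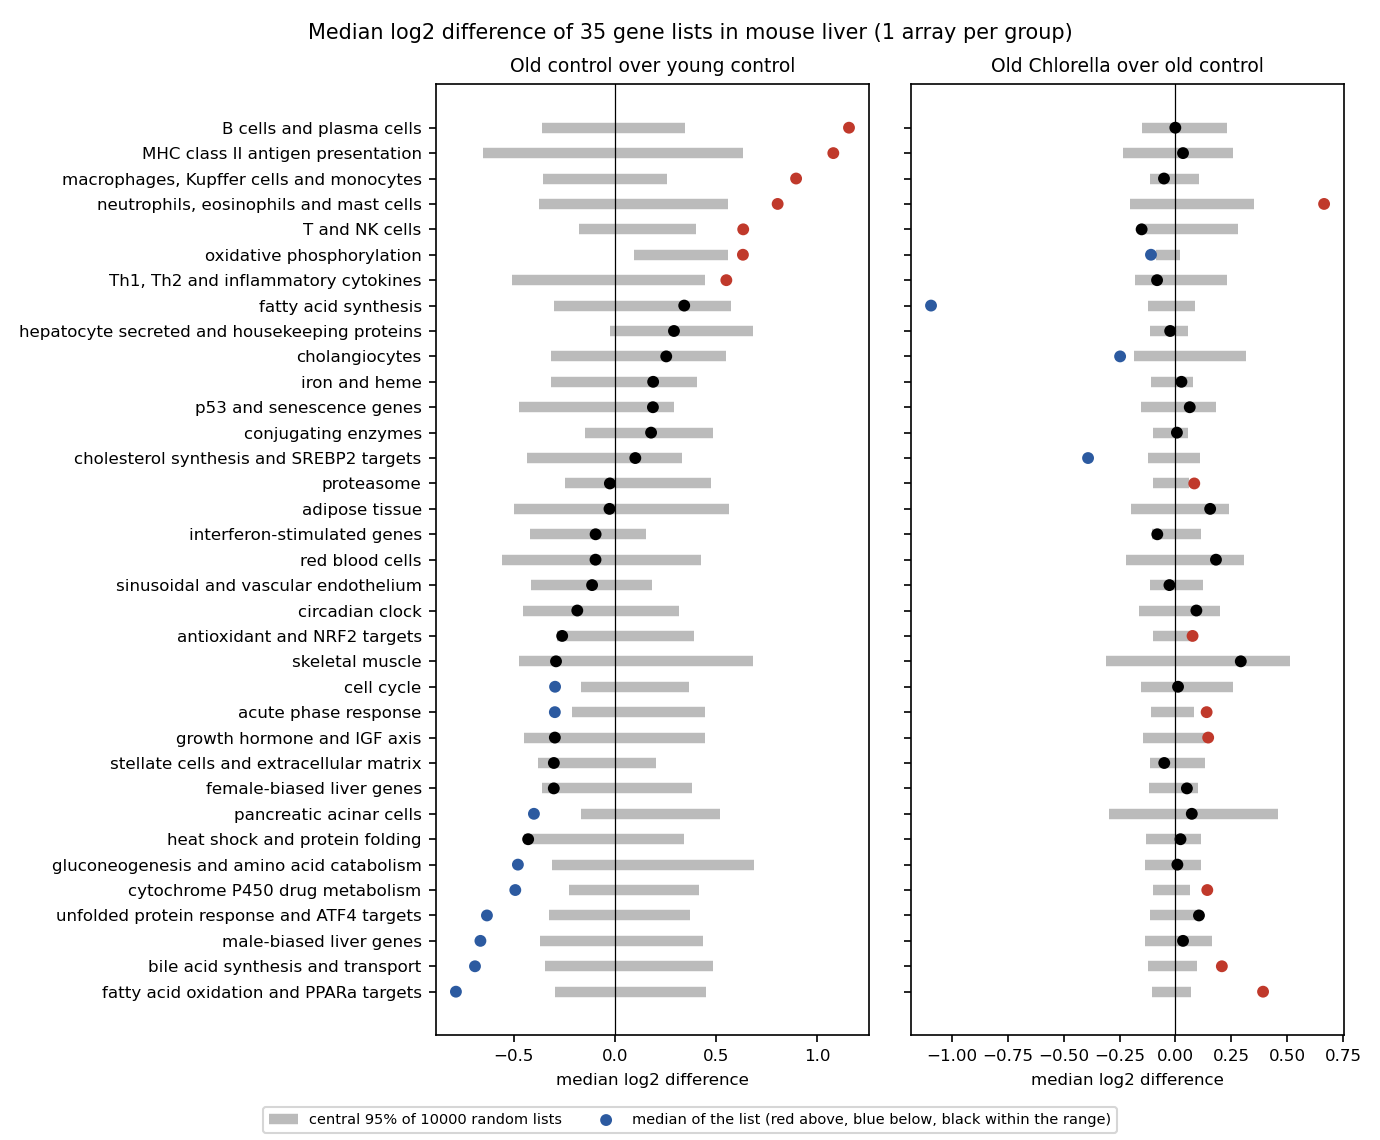
Median log2 difference of 35 gene lists, old control over young control at left and old Chlorella over old control at right, with 1 array per group. Dots are list medians and grey bars span the central 95% of 10000 random lists matched on mean signal. The B cell list reached 1.16 at left and the fatty acid synthesis list −1.09 at right.

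Outside the lists, the highest differences in old control were in Mrpl33, a mitochondrial ribosomal protein, at 12.8-fold, the integrin gene Itgae at 11.2-fold, Itgb3bp at 7.76-fold, the noncoding host gene Snhg1 at 7.29-fold and Wfdc17 at 7.27-fold. Ezr and Taf1d were 9.98-fold and 7.34-fold higher by their brightest probe sets. Another Ezr probe set was lower, at −0.84, and another of Taf1d gave −0.078. Hsf2bp was at least 8.61-fold higher. Lower were the cadherin gene Cdh1 at 7.35-fold, the mitochondrial carrier gene Slc25a30 at 6.17-fold, Scyl2 at 4.68-fold, Ppp6r1 at 4.60-fold and Nhsl1 at 4.55-fold. Zdhhc12 had a bound of −3.70 on the log2 scale. Nek2 was at least 5.78-fold lower by its brightest probe set and higher by 0.82 on the log2 scale by another.

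The other 19 lists stayed inside the random range. Those with a median of 0 or more were fatty acid synthesis at 0.34, hepatocyte secreted and housekeeping proteins at 0.29, cholangiocytes at 0.25, iron and heme at 0.19, p53 and senescence genes at 0.19, conjugating enzymes at 0.18 and cholesterol synthesis at 0.10. Heat shock genes had a median of −0.43, stellate cell and matrix genes −0.30, the growth hormone and IGF axis −0.30, skeletal muscle −0.29, antioxidant genes −0.26 and clock genes −0.19. Endothelial genes had −0.11, interferon-stimulated genes −0.10, red blood cell genes −0.10, adipose tissue genes −0.027 and the proteasome −0.025.

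The second comparison asks how livers of mice on Chlorella food differed from those on normal food at the same age. Genes of fatty acid synthesis, and to a smaller extent of cholesterol synthesis, were lower in old Chlorella, while PPARa targets and neutrophil genes were higher. The arrays of the 2 old groups were closer to each other than either was to young control: of 12489 genes, 167 were at least 2-fold higher and 105 at least 2-fold lower in old Chlorella. Simulated arrays with no difference gave a mean of 61.2 such genes and at most 84. Their noise may be too small for the 1541 differences with 1 array at the floor. Which direction held more genes depended on the processing: 160 were higher and 161 lower after quantile normalization, 125 and 139 after removal of an intensity trend, and 24 and 34 with a floor at the 70th percentile. Of the 35 lists, 8 had a median above and 4 a median below the random range. Apart from the neutrophil list, with 0.81 for age and 0.66 for diet, each of these had an age median of the opposite sign. PPARa targets had −0.79 and 0.39, and fatty acid synthesis 0.34 and −1.09. Several of these age medians lay inside the random range. Both comparisons use the single old control array, so its deviation cannot be told apart from a diet difference in these lists.

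Fatty acid synthesis genes were lower in old Chlorella in 13 of 19, at least 2-fold in 11, and higher in 0, with a median of −1.09 and a random range from −0.12 to 0.09. Acacb, the acetyl-CoA carboxylase at mitochondria, was 10.0-fold lower. Fasn, the fatty acid synthase, was 3.98-fold lower, with signals of 12586 in old control and 3161 in old Chlorella. The fatty acid elongase gene Elovl6 was 3.43-fold lower, the acetyl-CoA synthetase gene Acss2 3.40-fold, the lipogenic regulator Thrsp 3.33-fold and the ATP citrate lyase gene Acly 3.13-fold. Pnpla3, a lipid droplet enzyme induced with lipogenesis, was 3.91-fold lower, and Pnpla5, of the same family and outside the list, 11.3-fold. Acaca, Scd1 and Me1 had log2 differences of −1.27, −1.09 and −1.16.

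**Figure D2:**
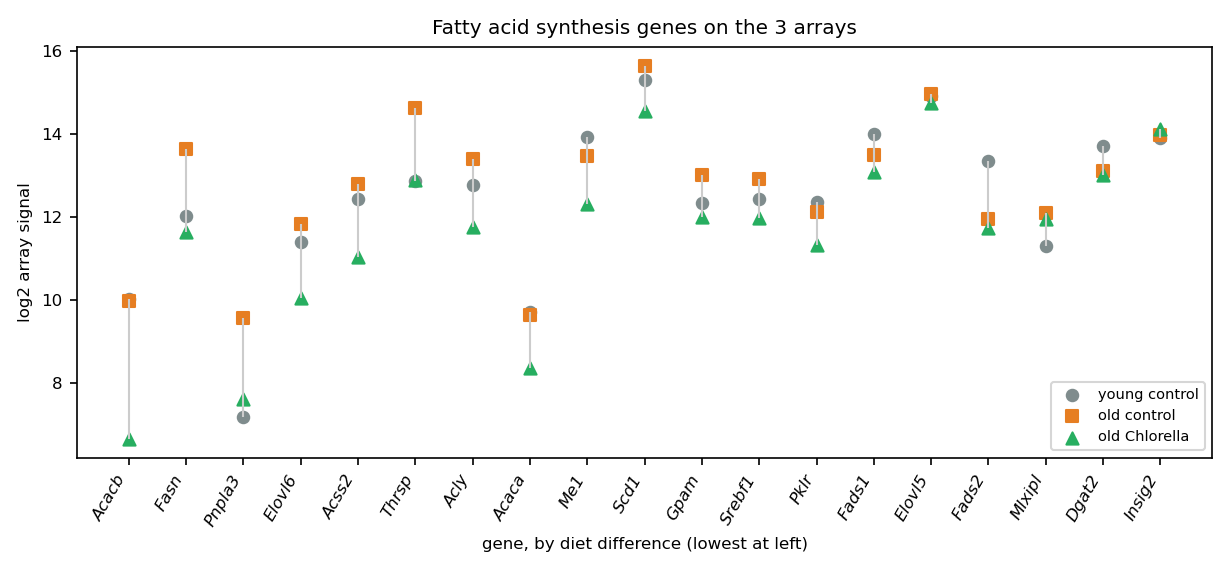
Log2 array signal of the 19 measured fatty acid synthesis genes on the 3 arrays, 1 point per array and gene, ordered by the difference between old Chlorella and old control. Old Chlorella lay below old control in Acacb by 10.0-fold and in Fasn by 3.98-fold, while Insig2 at the right end differed by 1.09-fold.

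Cholesterol synthesis and SREBP2 target genes were lower in 5 of 20 and higher in 0, with a median of −0.39 and a random range from −0.12 to 0.11. Fdps, the farnesyl diphosphate synthase, was 2.65-fold lower, Pmvk 2.40-fold, Mvd 1.91-fold and Dhcr7 1.63-fold. The fatty acid binding protein gene Fabp5 was 3.41-fold lower and Pdzk1ip1 3.78-fold. Fatty acid oxidation and PPARa target genes were higher in 7 of 26 and lower in 0, with a median of 0.39 and a random range from −0.11 to 0.07. Vnn1 was 2.94-fold higher, the omega-hydroxylase gene Cyp4a14 2.11-fold, Fgf21, a hormone of the fasted liver, 2.10-fold, and the lipase inhibitor gene Angptl4 1.85-fold.

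Neutrophil, eosinophil and mast cell genes were higher in 6 of 9 and lower in 0, with a median of 0.66. Csf3r, the receptor for granulocyte colony-stimulating factor, was 1.64-fold higher, S100a9 1.63-fold, S100a8 1.58-fold and Mmp9 1.51-fold. Bile acid genes had a median of 0.21 with 2 of 21 higher. They were Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.70-fold and the phospholipid exporter gene Abcb4 at 1.54-fold. Abcc2 and Nr0b2 were 1.49-fold and 1.47-fold higher. Cytochrome P450 genes had a median of 0.14 with 4 of 33 higher: Cyp2c37 at 2.01-fold, Cyp2c54 at 1.87-fold, Cyp2g1 at 1.77-fold and Cyp2b10 at 1.68-fold.

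The other lists outside the range had small medians. The acute phase list had 0.14 with 1 of 29 higher, which was Lcn2 at 2.14-fold. Lbp and Saa1 were 1.46-fold and 1.40-fold higher, and Il1rn had a log2 difference of 0.58, with probe sets from −0.015. The growth hormone and IGF axis had 0.15 with 1 of 15 higher, which was Cish, a feedback inhibitor of cytokine signalling, at 2.07-fold. Socs2 was 1.38-fold higher, with probe sets from −0.51 to 0.91. The proteasome had 0.084 with 0 of 31 at 1.5-fold, and its largest difference was 1.40-fold in Psmc5, followed by Psmd13 at 1.24-fold. The 4 Psmd13 probe sets ran from −0.29 to 0.31. Antioxidant and NRF2 target genes had 0.076 with 3 of 30 higher and 1 lower. The metallothionein gene Mt2 was 1.87-fold higher and Cbr3 1.78-fold. Mt1 was 1.81-fold higher by its brightest probe set and lower, at −0.30, by another.

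Cholangiocyte genes had a median of −0.25 with 3 of 10 lower and 1 higher. The stem cell marker gene Prom1 was 1.81-fold lower and the keratin gene Krt23 1.46-fold. Subunits of oxidative phosphorylation had −0.11 with 1 of 56 lower, which was Ndufs8 at 1.81-fold, though its 6 probe sets ran from −0.86 to 0.50. Ndufc1 and Atp5g1 were 1.27-fold and 1.26-fold lower. Of these 6 lists, acute phase, growth hormone, proteasome, antioxidant, cholangiocyte and oxidative phosphorylation, each was inside the random range under at least 1 alternative setting.

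Outside the lists, the highest differences in old Chlorella were in Ces5a, a carboxylesterase, at 6.06-fold, Fen1 at 4.03-fold, the collagen receptor gene Ddr1 at 3.22-fold, Nwd1 at 3.11-fold, the transcription factor gene Jun at 2.87-fold and Bex3 at 2.71-fold. Brd8 was 2.61-fold higher, Serpinb1a 2.53-fold and Crygn 2.53-fold. Several of these folds are over signals near the old control floor of 80.4. Ces5a, Fen1, Ddr1, Nwd1, Bex3 and Crygn had 92.9, 90.3, 85.6, 91.3, 93.8 and 94.4 there. Probe sets of one gene differed for Fen1, from 0.43 to 2.01, for Ddr1, from 0.63 to 1.69, and for Brd8, from 0.030 to 1.38. Hspbap1 was at least 4.10-fold higher and the lysosomal regulator Tfeb at least 3.32-fold. Sorbs3 was at least 2.98-fold lower. Rusc1 was at least 7.38-fold lower by its brightest probe set, but another probe set gave 0.58. Of the unfolded protein response list, which stayed inside the random range, Derl3 was at least 3.39-fold higher and Phgdh at least 4.16-fold lower by its brightest probe set, with 0.24 in another.

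The other 23 lists stayed inside the random range. Skeletal muscle had a median of 0.29, red blood cells 0.18, adipose tissue 0.15, the unfolded protein response 0.10, clock genes 0.093, pancreatic acinar genes 0.073 and p53 and senescence genes 0.064. Female-biased and male-biased liver genes had 0.051 and 0.034, MHC class II genes 0.034, iron and heme 0.027, heat shock genes 0.022, cell cycle genes 0.011, gluconeogenesis 0.0084 and conjugating enzymes 0.0064. B cells had −0.00077, hepatocyte proteins −0.024, endothelium −0.027, stellate cells −0.050, macrophages −0.051, interferon-stimulated genes −0.081, the cytokine list −0.082 and T and NK cells −0.15.

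The third comparison sets old Chlorella against young control. Of 12582 genes, 1019 were at least 2-fold higher and 683 at least 2-fold lower in old Chlorella, or 1403 and 442 after centring on the median of measured genes. The counts as reported stand against a mean of 321 in both directions in simulated arrays with no difference, whose noise may be too small for dim genes. The 5 immune cell lists as 1 set were higher in 60 of 89 members and lower in 1, with a median of 0.87. Old control over young control had 0.95, but both medians use the young control array, so a deviation of that array would enter them alike. Male-biased liver genes had a median of −0.38 with 8 of 20 lower. Fatty acid synthesis genes had a median of −0.75 with 11 of 19 lower and 1 higher, under the random range from −0.26 to 0.52.

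The last comparison asks which age differences were met by an opposite difference on the Chlorella food. Of 1927 genes with a 2-fold or larger age difference, 261, or 13.5%, had a diet difference that opposed it by at least 0.5 of its size on the log2 scale. The Wilson 95% interval of that share was 12.1% to 15.1% and treats genes as independent, which they are not. The share depended more on the processing: it was 5.08% with a floor at the 70th percentile, 7.30% in the ratio table, 19.7% with a floor at the 40th percentile and 34.5% with no floor. They were 129 of 1078 genes higher in old control and 132 of 849 lower. A further 22 genes that were 2-fold or more lower with age lay at the floor on both old arrays, had no diet difference and are left out of these counts. In 14 genes the diet difference went further in the same direction by as much.

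Among the largest opposed differences of genes above the floor on all 3 arrays, Vnn1 was 7.69-fold lower with age and 2.94-fold higher with diet, and Slc25a30 6.17-fold lower and 2.52-fold higher. Inhbe, which encodes a secreted activin subunit of hepatocytes, was 4.09-fold lower and 2.19-fold higher, and Bex3 3.77-fold lower and 2.71-fold higher. In the other direction, Pnpla5 was 5.81-fold higher with age and 11.3-fold lower with diet, and Pnpla3 5.23-fold and 3.91-fold. Ccdc180 was 5.02-fold higher and 2.91-fold lower, and the probe set of Ass1, a urea cycle enzyme, 4.79-fold and 2.36-fold. Msh5 was 3.85-fold higher and 2.64-fold lower, and Cnmd 3.49-fold and 2.00-fold. Some of these signals lay near the floor. Ccdc180, Ass1 and Msh5 had 78.6, 101 and 72.3 in young control, and Bex3 had 93.8 in old control. The Ass1 probe set had a log2 signal of 6.66 in young control, where Cps1, another urea cycle gene, had 14.84. Whether it reads the main Ass1 transcript is not known. Among genes above the floor on all 3 arrays, the largest age differences that diet did not oppose by that much were in Mrpl33, Itgae, Serpina4-ps1, Ezr and S100a8.

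Both differences use the old control array, whose chance deviation enters them with opposite signs. Arrays simulated with no difference had a covariance of −0.048 between age and diet differences, and the observed covariance was −0.10. Of a mean of 362 genes that reached 2-fold for age on those arrays, 17.9% were opposed, a larger share than the observed 13.5%. Arrays simulated with the observed age difference and no diet difference gave 4.25% opposed genes, with a range of 3.19% to 5.55%, and a covariance of −0.048. That share is over a mean of 2525 genes at 2-fold, more than the 1927 observed. The observed age difference already holds the old control array's deviation, and it was given to both old arrays before noise was added again. The share may therefore be too low, and how far this moves the simulated counts was not tested. In numbers of genes, the means were 64.6 and 107, against 261 observed. Read from separate probe sets of the same gene, the share was 7.43% or 3.69%, against 7.27% within 1 probe set for the same 4277 genes, and the covariance was −0.047 or −0.043 against −0.080. Of 2-fold differences, 39 genes were higher with age and lower with diet, against a mean of 9.64 on arrays simulated with the observed age difference and no diet difference, and 45 were lower and then higher, against 8.63. The simulations hold no variation between pools and may understate the noise of dim genes. The old control group has 1 array, so the whole excess may come from that array. Variances of the 3 differences over 10527 genes gave each array's own deviation. Its SD was 0.67 in young control, 0.30 in old control and 0.16 in old Chlorella. Noise between probe sets of the same gene gave 0.37, 0.22 and 0.19. Across genes, old control deviated beyond that noise and old Chlorella did not. A diet difference that opposes age differences also counts as a deviation of old control, so this does not decide.

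**Figure D3:**
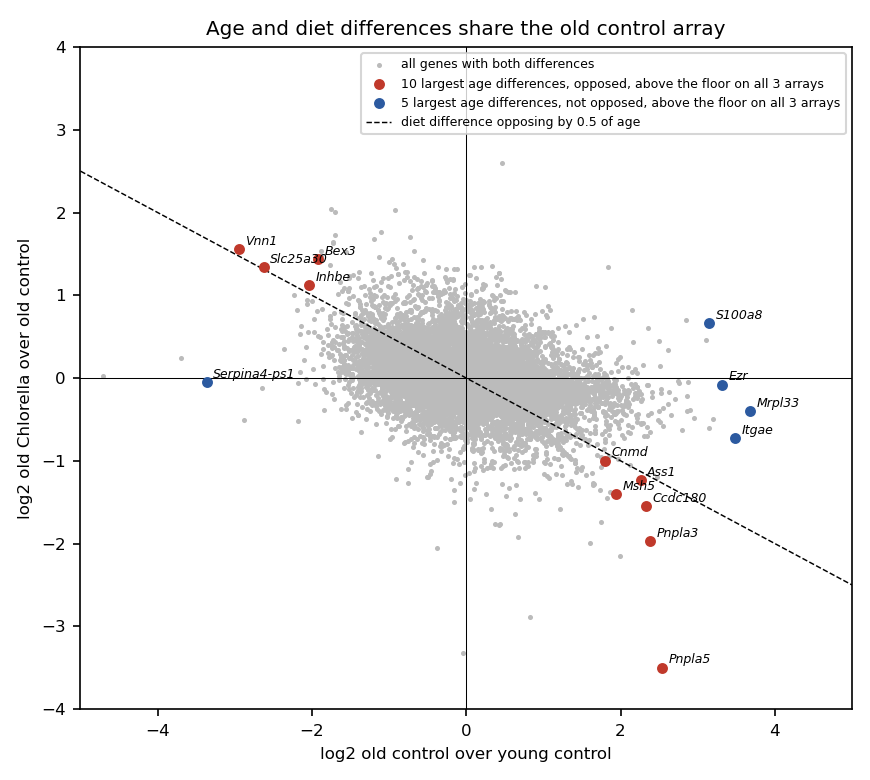
Log2 difference of old control over young control on the horizontal axis and of old Chlorella over old control on the vertical axis, 1 point per gene. Among genes above the floor on all 3 arrays, red points are the 10 largest age differences opposed by at least 0.5 of their size, beyond the dashed line, and blue points the 5 largest not opposed by that much. Pnpla5 lay lowest, with a diet difference of −3.50.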

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

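All tests in this part were chosen after the result was seen. The control probe sets and the probe sets without a single gene symbol enter no gene count and no gene list above, and both held differences between groups. The 3′ over 5′ log2 ratio of the Pcx control probe sets was higher than in young control by 1.79 in old control and by 1.88 in old Chlorella. For Actb the values were 0.38 and 0.40, and for Gapdh 0.22 and 0.17. The young control array thus stood apart from both old arrays in all 3 control genes, while the old arrays differed little from each other.

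Among probe sets with no single gene symbol, 17.7% differed at least 2-fold between old and young control, 414 of them higher and 141 lower in old control. Between old Chlorella and old control 3.02% did, 69 higher and 31 lower.

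The oxidative phosphorylation list had for the age difference a median at percentile 98.1 of random lists matched on genomic gene length and signal together. Xist, which is transcribed from the inactive X chromosome, was lower in young control than in both old groups on all 3 of its probe sets. The log2 signals were 10.04, 6.23 and 10.31 in young control, 11.27, 8.25 and 11.69 in old control, and 11.33, 7.55 and 11.42 in old Chlorella.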

How the results depend on the processing

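With 1 array per group, no array could be left out, and no paired analysis was possible because each group has 1 array. Signal over background limits the dim genes: the SD between probe sets of the diet difference was 0.40 in the dimmest of 5 bins and 0.15 in the brightest. Of list medians outside the random range, 10 of 16 for age and 6 of 12 for diet stayed outside it under every alternative that gave a value, among them fatty acid synthesis for diet, from −1.27 to −0.85, and B cells for age, from 1.02 to 1.75. None of the 28 changed sign. Over all settings, 9 values of named genes that differed 1.5-fold or more as reported changed sign. Of the other values of named genes, 1468 moved by no more than the SD between probe sets and 123 by more. Sign changes of smaller differences were not counted apart. Removing trends with intensity and genomic gene length, chosen after seeing the data, left all counts within 1.5 times. So did leaving out differences whose sign the floor turned, also chosen then, which gave 13.6% opposed and a bile acid median of 0.22 for diet.

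Counts of 2-fold genes moved with the floor by construction. With a floor at the 40th percentile, 409 were higher and 231 lower for diet, and 19.7% of age differences were opposed. At the 70th percentile, 636 were higher for age, 24 higher and 34 lower for diet, 503 higher for old Chlorella over young control, and 5.08% were opposed. With no floor, 3187 were higher and 2346 lower for age, 2157 and 1504 for diet, 3361 and 1863 for old Chlorella over young control, and 34.5% were opposed. In the ratio table, which holds fewer probe sets, 56 were higher and 50 lower for diet and 7.30% were opposed. Averaging all probe sets gave 17.1% opposed, and the cause was not tested.

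Quantile normalization gave 161 lower genes for diet, and the share of higher genes among 2-fold differences was 49.8% against 61.4% as reported, and 47.3% after the intensity trend was removed. Centring on the median of measured genes shifted all age differences by 0.15 and those of old Chlorella over young control by 0.14. It gave 543 lower genes for age and 442 for old Chlorella over young control, with 73.0% higher against 55.3% and 76.0% against 59.9%. These shifts follow from the constant added to each array.

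Signs reversed in few named genes at 1.5-fold or more as reported. The same held for list medians outside the random range as reported or under the alternative. Nek2 for age had 0.62 after quantile normalization, and 0.82 without probe sets of shared sequence and in the ratio table. Ezr for age had −0.84 in both of the latter. Without those probe sets, Mt1 for diet had −0.30, Rusc1 for diet 0.13, Ndufb2 for age −0.15 and the gluconeogenesis list for diet a median of −0.15. The Ndufb2 value came from a probe set at the floor on 1 array. With all probe sets averaged, Pdia6 for age had 0.082 and the cytokine list for diet 0.34. These settings read other probe sets of the gene. So did quantile normalization for Nek2. It keeps the order of signals within an array, and the probe set reported lay above the floor in young control and under it in old control.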

Other observations

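All tests in this part, and the bounds by which they were read, were chosen after the result was seen. Clock genes differed little between the old groups apart from Nr1d1 and Per2. Nr1d1, a repressor of the clock loop, had a log2 difference of −1.58 in old Chlorella against old control and Per2 one of −0.70, while Arntl had 0.093 and Cry1 −0.10. Against young control, old control had 1.22 in Nr1d1 and 0.82 in Per2. Of red blood cell genes, Hbb-b2 was higher in old control with 1.55 and lower in old Chlorella with −0.63, and Alas2 had 0.64 and −0.77.

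Immune cell genes were higher in old control than in young control, and in old Chlorella their median against young control was 0.87. Both medians use the young control array, so a deviation of that single pool stays open. The 5 lists together had a median age difference of 0.95, with 62 of 91 members higher and 1 lower. A trend with genomic gene length is argued against by random lists matched on that length and signal, among which the median lay at percentile 100. Lengths of transcripts were not used here, so a gain of short over long transcripts on the old arrays stays open. A lower share of hepatocytes, with the other cells kept in proportion, would raise markers of the other resident cell types as well. Stellate cell, endothelial and cholangiocyte genes together had a median of −0.12. More blood in the old livers cannot be told apart from more immune cells in the tissue, because red blood cell genes went both ways, with 3 of 10 higher and 3 lower and a median of −0.096. Age, and any sensitization the labels leave out, stay open and untested.

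Male-biased liver genes were lower in old control although all mice are labelled female. A male mouse in the young pool cannot be told apart from a difference between females. Of 11 Y-linked probe sets 0 were above the floor on the young array, but no male liver was analysed here to show the level a male would give. Xist was lower in young control than in old control by 1.23, 2.02 and 1.38 on its 3 probe sets. One male among 6 would lower it by 0.26 and more males by more, so the size of these differences does not decide. A trend with genomic gene length is argued against by the percentile of 0.01 among lists matched on that length and signal, while one with transcript length stays open. A lower share of hepatocytes, with the other cells kept in proportion, would raise the markers of all other cell types alike. These moved apart: the median of the 5 immune lists exceeded that of stellate cell, endothelial and cholangiocyte genes by 1.07, with quartiles of 0.36 to 1.45 against −0.45 to 0.33. That argues against this case only. A gain of immune cells would also lower the share without raising the other markers, so a lower share stays open. Hepatocyte proteins, with a median of 0.29, decide nothing, since most lie near the top of the signal range and members went both ways, with −1.32 in Apob, −1.03 in Hnf4a and −0.92 in Cebpa. Age and a deviation of the single young pool stay open and untested.

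Fatty acid synthesis genes were lower in old Chlorella than in old control. An old control array that alone was out of place cannot be told apart. The median of old Chlorella over young control was −0.75, under the random range, but these pools also differ in age, so no array here shows where old control should lie. Less food in the gut at collection may lower the same genes. It cannot be told apart from the diet itself, because PPARa targets were higher as in fasting while gluconeogenesis genes had a median of 0.0084. Another time of day at collection also cannot be told apart: the median absolute difference of the clock list lay at percentile 53.8, but Nr1d1 differed 2.99-fold. An effect of the Chlorella food on lipogenesis therefore remains a hypothesis, and a deviation of the single old Chlorella pool stays open with it.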
